A study of Mus musculus with 12 samples.

How the data were processed

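Poly(A) RNA of mouse embryonic fibroblasts was sequenced on day 6 of adipocyte differentiation in 12 libraries, 3 for each of 4 genotypes. Per the labels' protocols, confluent cells received 0.5 mM IBMX, 1 µM dexamethasone, 2 µM rosiglitazone and 10 µg/ml insulin for 48 h, libraries were made from 280 ng RNA with 12 cycles of PCR, and the pool was read in 7 lanes for 51 cycles from 1 end. Samples were grouped by the genotype in their labels.

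The deposited files hold raw counts of reads per Ensembl gene. The submitters' processing notes name FastQC, TopHat2 2.0.9, Bowtie2 2.1.0, HTSeq 0.5.4 and DESeq, with the genome builds mm9 and NCBIM37; the strand setting and the counting mode are not given in the sources used here. Each file lists 37991 gene identifiers and 5 lines that name no gene. Those lines took between 24.2% and 24.9% of each library, most of it alignments that were not unique, and were left out of library sizes and tests. Reads that map to several places are thus missing, which lowers genes with near-identical copies. Symbols came from a mouse GENCODE annotation of a later build, used for names and for which genes lie near each other, and matched 32919 identifiers. No coordinates are given.

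Computed here from those counts were CPM, fold changes and tests. The main test was edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr with the genotype, robust dispersions and the quasi-likelihood test with all 12 libraries in 1 fit of genotype means, so that the genotypes share their estimate of spread. Genes at a Benjamini-Hochberg adjusted p under 0.05 were called, without a fold minimum. TMM factors lay between 0.986 and 1.01, and the common biological coefficient of variation was 0.105. Comparisons were each mutant with WT, the libraries labelled DKO with each single mutant, and the interaction. Gene lists, 31 in number and fixed before the data were examined, were tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01 where at least 5 members were tested, which held for 30; the erythroid list had 0 tested members. Each test was repeated with an estimated correlation and with fry. None of the camera calls in any comparison held with an estimated correlation. With fry, 11 of 14 held for the libraries labelled DKO against WT and 8 of 14 for Ing1-KO against WT. For DKO against Ing1-KO 3 of 18 held, and in the other comparisons none did. Fry asks whether the members of a list changed together, and not whether they changed more than other genes. Errors are SD over 3 libraries for CPM and SE for log2 fold changes. The SE is an approximation, the absolute log2 fold change divided by the square root of its quasi-likelihood F statistic.

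Genes are named by a rule fixed before the data were examined: the targets; the called genes with the largest changes at a mean of at least 5 CPM whose library values do not overlap, 10 each way for the libraries labelled DKO against WT, fewer elsewhere, without predicted genes, RIKEN clones and pseudogenes; the called list members with the smallest adjusted p, up to 4 per list and comparison; and 14 genes of adipogenesis and the cell cycle whatever their values. Of the genes the rule takes, 3 are not reported here and are left out of the counts of named calls.

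Alternatives fixed in advance were RLE and upper-quartile factors, no filter, a mean of at least 5 CPM, DESeq2 1.42.0, the legacy quasi-likelihood fit, the replicate number as a block, leaving out each library, a fold of at least 2, and fitting only the 6 libraries compared. Limma-voom and an adipocyte score as covariate, the mean log2 CPM of the adipocyte list, were added after the data had been seen. Replicates of a genotype differed by more than sampling noise in every pair. The steps were also tested on simulated counts drawn from the real means, dispersions and library sizes with 200 genes changed: for the libraries labelled DKO against WT it recovered 61.2%, 73.1% and 93.9% of genes changed 1.5-fold, 2-fold and 4-fold, with 10 false calls among 16163 genes. A simulated list lowered 1.5-fold was called, and 0 of 24 lists sharing none of its genes were. Genes were simulated independently of each other, whereas members of real lists varied together. For the libraries labelled DKO against WT the estimated correlation of the adipocyte list was 0.764. False list calls in the real data therefore cannot be judged from this simulation.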

Results

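Transcript levels were measured by poly(A) RNA sequencing in mouse embryonic fibroblasts on day 6 of differentiation into adipocytes. The cells came from male embryos and had been cultured for 4 passages before a hormonal cocktail was added to the confluent cultures. Per the labels, the embryos were wild type (WT), lacked Gadd45a (Gadd45a-KO), lacked Ing1 (Ing1-KO) or lacked both (DKO), with 3 libraries per genotype and 12 in all. Gadd45a encodes a stress-induced protein linked to DNA repair and demethylation, and Ing1 a reader of methylated histone H3 in a histone deacetylase complex. Gene reads per library ranged from 42891627 in DKO replicate 1 to 52860419 in Gadd45a-KO replicate 1, and 16163 genes were tested. The labels do not say whether replicates came from separate embryos or cultures, so the p-values measure the spread between these libraries.

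The targeted genes were examined first, because they check the labels. Ing1 followed its label: its level was 45.4 ± 2.26 CPM (SD, n = 3) in WT and 46.0 ± 1.47 CPM in the libraries labelled Gadd45a-KO, against 1.22 ± 0.326 CPM in Ing1-KO and 0.915 ± 0.234 CPM in the libraries labelled DKO. Gadd45a (ENSMUSG00000036390 in the files; Ing1 is ENSMUSG00000045969) went against its label. It stood at 15.8 ± 1.82 CPM in WT and 15.6 ± 2.55 CPM in Ing1-KO, but at 143 ± 1.75 CPM in the libraries labelled Gadd45a-KO and 140 ± 1.90 CPM in those labelled DKO. The lowest of those 6 libraries, at 138 CPM, lay 7.49 times above the highest of the other 6, at 18.4 CPM. Counts per gene do not show which exons the reads cover, so they cannot tell whether an intact transcript was made. All 4 genotype names rest on the labels where Gadd45a is concerned, those of WT and Ing1-KO included, and so do the directions given.

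**Figure D1:**
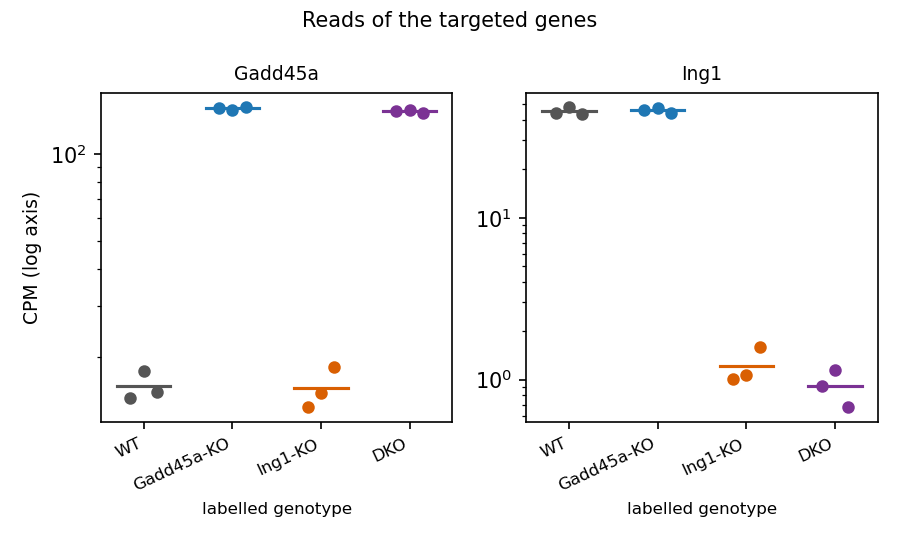
CPM of Gadd45a and Ing1 on a log axis for each of the 12 libraries, by labelled genotype, with a bar at each mean of 3. Gadd45a lies between 138 and 144 CPM in the 6 libraries labelled Gadd45a-KO or DKO and between 13.4 and 18.4 CPM in the others, and Ing1 lies below 1.60 CPM in the 6 libraries labelled Ing1-KO or DKO.

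The comparison of the libraries labelled Gadd45a-KO with WT asked what loss of Gadd45a alone does to the differentiating cells. By edgeR no gene outside the targeted locus passed the test. Gadd45a rose by a log2 fold change of 3.18 ± 0.108 (SE; adjusted p = 2.08e-07, edgeR quasi-likelihood test), and E230016M11Rik, a non-coding gene that overlaps Gadd45a in the reference annotation, fell by 3.03 on the log2 scale from 1.06 CPM in WT (SE 0.249; adjusted p = 0.000756). E230016M11Rik was outside the rule for named genes and was chosen after its values were seen; where overlapping genes share sequence, reads cannot be assigned to either with certainty. At an unadjusted p under 0.05 there were 886 genes, where chance gives 808. DESeq2 called 3 genes higher and 4 lower, and limma-voom 1 and 1. Without Gadd45a-KO replicate 1, whose mean of the leukocyte marker list, 5.44 log2 CPM, lay below the 6.76 and 6.63 of replicates 2 and 3, edgeR called 30 higher and 3 lower. Without WT replicate 1 it called 2 higher, and without WT replicate 3 or Ing1-KO replicate 2 it called 2 lower. Fat-cell genes lay lower in these libraries without passing: Fabp4, the fatty acid binding protein of adipocytes, was at 486 ± 80.0 CPM against 1008 ± 331 CPM in WT (adjusted p = 0.88), and Adipoq, which encodes adiponectin, at 53.1 ± 10.1 against 128 ± 51.8 CPM (adjusted p = 0.88). All 30 tested members of the list of adipocyte identity and lipid droplet genes had a negative log2 fold change, with a median of -1.03 and none called. WT replicate 2, with a list mean of 4.62 log2 CPM, lay nearer to these libraries (4.48, 4.53 and 4.19) than to WT replicates 1 and 3 (5.57 and 5.49). The list was called by camera (adjusted p = 5.78e-14; adjusted p = 0.411 with an estimated correlation), as were 13 other lists in this comparison; of these 14, 12 were lower and 2 higher, and none held with an estimated correlation. Among the lower was cholesterol synthesis, with all 24 tested members negative and a median of -0.19 (camera adjusted p = 2.95e-14). The mean of that list in WT replicate 2, 5.655 log2 CPM, lay close to the 5.636 of Gadd45a-KO replicate 2.

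The comparison of Ing1-KO with WT asked the same of Ing1, in libraries whose Gadd45a genotype rests on the labels. By edgeR 388 genes were higher and 311 lower. Cartilage genes were among the largest rises. Acan, which encodes the cartilage proteoglycan aggrecan, rose from 3.41 ± 0.238 to 33.1 ± 22.1 CPM (log2 fold change 3.28 ± 0.500 SE, adjusted p = 0.00979), and Comp, a cartilage matrix protein, by 2.49 ± 0.435 on the log2 scale (adjusted p = 0.0164). Col10a1, a collagen of hypertrophic cartilage, rose by 2.27 ± 0.355 (adjusted p = 0.0106). Of 22 tested cartilage and bone markers 4 rose and none fell (camera adjusted p = 0.000129; adjusted p = 0.242 with an estimated correlation). Penk, the enkephalin precursor, rose by 3.81 ± 0.741 on the log2 scale (adjusted p = 0.0251), with a wide spread of 221 ± 185 CPM, and Eln, which encodes elastin, went from 194 ± 22.3 to 919 ± 225 CPM (adjusted p = 0.0224). Apart from Ing1, the falls taken by the rule were those of Cyp4b1, Pcdh20, Sbsn, Nt5e and Ptger3, by 1.42, 1.36, 1.27, 1.26 and 1.17 on the log2 scale, with edgeR adjusted p-values from 0.0162 to 0.0484. Nt5e, the ecto-nucleotidase CD73, went from 70.7 ± 14.0 to 29.4 ± 6.51 CPM.

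Among imprinted genes, which are expressed from 1 parental allele, 6 of 27 tested members rose in Ing1-KO and none fell (camera adjusted p = 9.67e-05; adjusted p = 0.282 with an estimated correlation). Mest rose from 44.3 ± 7.62 to 180 ± 44.4 CPM (adjusted p = 0.00163), and Igf2, a fetal growth factor, from 745 ± 160 to 1790 ± 641 CPM (adjusted p = 0.0341). In the list of positional genes 6 of 49 rose and 3 fell, with Barx1 up by 3.12 ± 0.305 and Pax9 by 1.73 ± 0.195 on the log2 scale (adjusted p = 0.000977 and 0.00207), while Hoxd3 fell by 0.60 (adjusted p = 0.0118). Barx1 and Pax9, transcription factors of the developing face, were scarce, at 1.66 and 3.17 CPM in Ing1-KO. That list was called by camera (adjusted p = 0.0342; adjusted p = 0.282 with an estimated correlation), but not without Ing1-KO replicate 3 (adjusted p = 0.207), Gadd45a-KO replicate 1 (0.0612) or WT replicate 1 or 3 (0.0607 and 0.111).

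Genes of cholesterol synthesis and of the cell cycle were lower in Ing1-KO. Of 24 tested SREBP2 targets 10 fell and none rose, with a median log2 fold change of -0.27 (camera adjusted p = 2.26e-15; adjusted p = 0.282 with an estimated correlation). The fall was not particular to Ing1-KO. In the libraries labelled Gadd45a-KO against WT all 24 were negative, with a median of -0.19 and none called (camera adjusted p = 2.95e-14, and 0.401 with an estimated correlation). The list mean of Ing1-KO replicate 1, 5.653 log2 CPM, lay close to the 5.655 of WT replicate 2. Of 35 proliferation genes 6 fell, and all 35 had a negative log2 fold change, with a median of -0.34 (camera adjusted p = 3.8e-19; adjusted p = 0.282 with an estimated correlation); adjusted over the list alone, 30 fell. Rrm2, a subunit of ribonucleotide reductase, went from 68.3 ± 3.18 to 50.5 ± 2.12 CPM (adjusted p = 0.00487). Cdkn2a, whose products block the cell cycle, rose from 40.3 ± 3.86 to 58.4 ± 3.34 CPM (adjusted p = 0.00487). Adipocyte genes spread widely: Fabp4 was at 1219, 406 and 98.8 CPM in the 3 Ing1-KO libraries and Adipoq at 146, 44.1 and 9.14 CPM, with adjusted p = 0.53 and 0.505, and 2 of the 30 list members fell, Fabp5 and Cav1 (camera adjusted p = 9.96e-07; adjusted p = 0.554 with an estimated correlation). The median log2 fold change of that list was -0.76, -1.86 without Ing1-KO replicate 1 and -0.30 without Ing1-KO replicate 3. These counts depend on single libraries. Without Ing1-KO replicate 2 they were 63 and 38, and without WT replicate 1, 2 or 3 they were 99 and 68, 76 and 76, or 101 and 82; leaving out Gadd45a-KO replicate 1 gave 636 and 519, Ing1-KO replicate 3 gave 698 and 505, Ing1-KO replicate 1 gave 539 lower genes, Gadd45a-KO replicate 3 gave 249 and 178, and DKO replicate 1 gave 244 and 181. Fitting only the 6 libraries compared called 217 and 171, and DESeq2 645 and 611; a fold of at least 2 left 109 and 41, and an adipocyte score as covariate, added after the data had been seen, gave 780 and 808. Of 54 named calls 13 passed in all 12 fits that left out a library; 38 were lost without Ing1-KO replicate 2 and 38, 37 and 34 without WT replicates 1, 2 and 3.

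The comparison of the libraries labelled DKO with WT asked what combined loss does. By edgeR 960 genes were higher and 1146 lower. Many genes of the fat-cell programme fell. Of 30 adipocyte identity and lipid droplet genes 24 fell and none rose, with a median log2 fold change of -3.70 (camera adjusted p = 8.56e-25; adjusted p = 0.298 with an estimated correlation); adjusted over the list alone, 28 fell. Fabp4 went from 1008 ± 331 to 72.1 ± 5.95 CPM (log2 fold change -3.81 ± 0.726 SE, adjusted p = 0.0131), and Adipoq from 128 ± 51.8 to 3.99 ± 1.51 CPM (-5.00 ± 0.894, adjusted p = 0.0107). Plin1, which coats lipid droplets, went from 63.6 ± 24.4 to 2.00 ± 0.552 CPM (-4.98 ± 0.878, adjusted p = 0.0105). Pparg, the transcription factor that drives adipogenesis, fell by 3.05 on the log2 scale (SE 0.628, adjusted p = 0.0163), Cebpb by 0.30 and Cebpd by 0.52. Cebpa, at a log2 fold change of -1.04 (adjusted p = 0.0622), and Slc2a4, the insulin-regulated glucose transporter, at -2.25 (adjusted p = 0.0547), did not pass. Dlk1, a marker of preadipocytes, was at 106 ± 15.2 CPM against 108 ± 5.84 CPM in WT (adjusted p = 0.966), and Cdkn1a, a cell cycle inhibitor, at 447 ± 35.0 against 435 ± 15.2 CPM (adjusted p = 0.746). Lep, which encodes leptin, fell from 2.00 ± 1.10 CPM to near the floor, 0.0216 CPM (adjusted p = 0.00549). The falls taken by the rule, apart from Ing1, were Elovl3, Gpd1, Cidec, Mrap, Lrg1, Pck1, Adipoq, Acvr1c and Plin1, with log2 fold changes from -6.08 to -4.98. Cidec, a protein of lipid droplet fusion, went from 269 ± 120 to 6.43 ± 1.11 CPM (adjusted p = 0.00885), and Gpd1, glycerol-3-phosphate dehydrogenase, from 315 ± 140 to 7.01 ± 2.86 CPM (adjusted p = 0.00983).

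**Figure D2:**
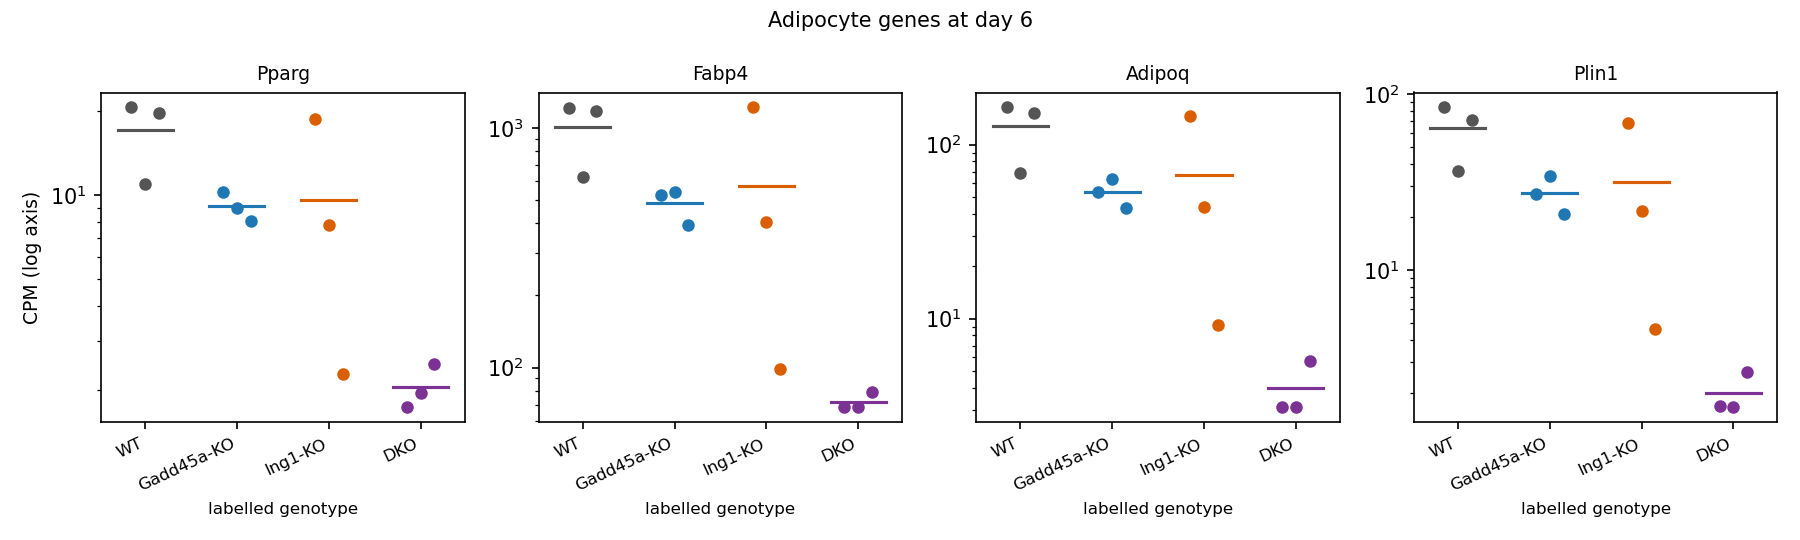
CPM of Pparg, Fabp4, Adipoq and Plin1 on a log axis for each of the 12 libraries, by labelled genotype, with a bar at each mean of 3. The mean of Fabp4 is 1008 CPM in WT, 486 in the libraries labelled Gadd45a-KO, 575 in Ing1-KO and 72.1 in those labelled DKO, and the 3 Ing1-KO libraries spread from 98.8 to 1219 CPM.

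Lipid metabolism genes fell with them. Of 26 fatty acid synthesis genes 18 fell (camera adjusted p = 4.92e-15; adjusted p = 0.298 with an estimated correlation), with Scd1, a fatty acid desaturase, at 163 ± 32.0 CPM against 2694 ± 824 CPM in WT (adjusted p = 0.00885) and Fasn, the fatty acid synthase, down by 1.01 on the log2 scale (adjusted p = 0.0131). Of 21 triglyceride genes 17 fell and 1 rose (camera adjusted p = 1.09e-13; adjusted p = 0.309 with an estimated correlation). Of 24 cholesterol synthesis genes 19 fell, with a median of -0.42 (camera adjusted p = 2.66e-21; adjusted p = 0.298 with an estimated correlation). Fatty acid oxidation had 13 of 26 members down and 1, Cpt1a, up (camera adjusted p = 4.65e-11; adjusted p = 0.315 with an estimated correlation), and oxidative phosphorylation 12 of 49 down, with a smaller median of -0.19 (camera adjusted p = 2.46e-08; adjusted p = 0.496 with an estimated correlation). Among acute phase and secreted proteins 7 of 20 fell and 2 rose (camera adjusted p = 6.46e-06; adjusted p = 0.451 with an estimated correlation). The chemokines Ccl2 and Ccl7 fell by 0.78 and 0.73 on the log2 scale (adjusted p = 0.000573 and 0.000388).

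Markers of other cell types moved in the same libraries. All 25 tested macrophage and leukocyte markers had a positive log2 fold change, with a median of 0.89, and 10 rose (camera adjusted p = 4.47e-13; adjusted p = 0.315 with an estimated correlation). Ptprc, the pan-leukocyte antigen CD45, went from 74.1 ± 7.72 to 135 ± 3.06 CPM (adjusted p = 0.0236), and Adgre1, the macrophage antigen F4/80, from 267 ± 24.2 to 588 ± 5.80 CPM (adjusted p = 0.0297). Among the largest rises were Fcrls, Aif1 and Cxcr4, all known in myeloid cells or leukocytes, by 2.04 ± 0.402, 1.64 ± 0.328 and 1.70 ± 0.438 on the log2 scale (adjusted p = 0.0147, 0.0151 and 0.0324), and Hpgd, a prostaglandin dehydrogenase, by 2.01 ± 0.406 (adjusted p = 0.0154). Eln, Npl and Slc13a3 rose by 2.34, 1.81 and 1.78 on the log2 scale. Of 25 contractile genes 8 rose (camera adjusted p = 5.14e-08; adjusted p = 0.451 with an estimated correlation), with Actg2, a smooth muscle actin, at 544 ± 211 against 211 ± 33.8 CPM (adjusted p = 0.0174); Actg2 lies within 20 Mb of Gadd45a in the reference annotation. The mean of the contractile list was 9.06 and 9.18 log2 CPM in DKO replicates 1 and 2 but 8.63 in DKO replicate 3, below the 8.65 of WT replicate 2. Cartilage and bone markers had 6 of 22 members up and 1 down (camera adjusted p = 0.0414; adjusted p = 0.314 with an estimated correlation), Acan and Col10a1 among the rises. That list was not called without DKO replicate 1 (adjusted p = 0.0828), WT replicate 1 or 3 (0.0557 and 0.0571), Gadd45a-KO replicate 1 (0.145) or Ing1-KO replicate 1 or 3 (0.052 and 0.0652). No proliferation gene was called by edgeR, over all genes or adjusted over the list alone. The counts depend on single libraries: without DKO replicate 1 they were 160 higher and 173 lower, without DKO replicate 2 408 and 408, without WT replicate 1 121 and 175, without WT replicate 3 279 and 363, without WT replicate 2 593 higher, and without Gadd45a-KO replicate 1 1472 higher. A fold of at least 2 left 168 and 360, fitting only the 6 libraries compared gave 1487 higher, and the adipocyte score as covariate, which is itself an outcome of the genotypes, left 20 and 25. Of 114 named calls 30 passed in all 12 fits that left out a library; 80, 47 and 17 were lost without DKO replicates 1, 2 and 3, and 70, 14 and 45 without WT replicates 1, 2 and 3.

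**Figure D3:**
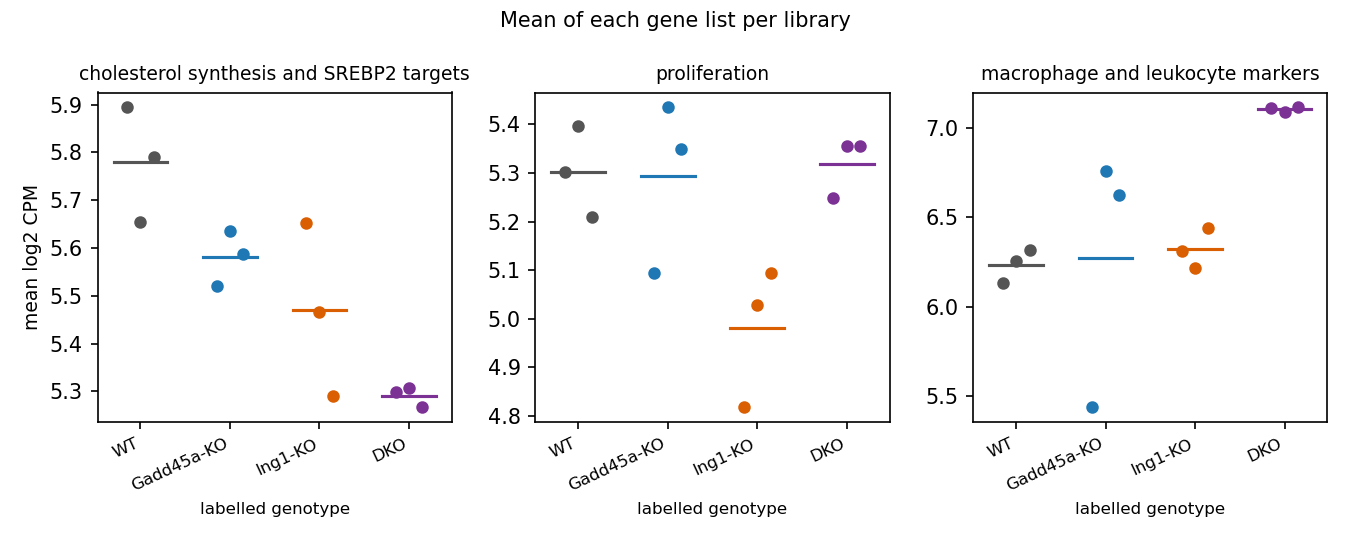
Mean log2 CPM of the tested members of 3 gene lists for each of the 12 libraries, by labelled genotype, with a bar at each mean of 3. The cholesterol list lies between 5.27 and 5.31 in the libraries labelled DKO and between 5.66 and 5.89 in WT; the leukocyte list lies between 7.09 and 7.12 in the libraries labelled DKO and at 5.44 to 6.76 in those labelled Gadd45a-KO.

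Comparing the libraries labelled DKO with each single mutant asked what the second lesion adds. Against the libraries labelled Gadd45a-KO, 203 genes were called, 107 higher and 96 lower. No adipocyte identity gene was among them, although all 30 had a negative log2 fold change, with a median of -2.40, and 18 fell when adjusted over the list alone (camera adjusted p = 1.26e-19; adjusted p = 0.409 with an estimated correlation). Upper-quartile scaling changed the share of higher calls from 52.7% to 41.9%. The count was 95 with the replicate number as a block, 1253 by DESeq2, 424 when only the 6 libraries compared were fitted, 35 at a fold of at least 2, and 69 with the adipocyte score as covariate. Leaving out a library moved it in every case: to 99, 90 and 74 without WT replicates 1, 2 and 3, to 337, 68 and 44 without Gadd45a-KO replicates 1, 2 and 3, to 501, 97 and 590 without Ing1-KO replicates 1, 2 and 3, and to 6, 17 and 494 without DKO replicates 1, 2 and 3. Against Ing1-KO, 956 genes were higher and 931 lower. Proliferation genes were higher, 18 of 35 called with none lower (camera adjusted p = 1.15e-16; adjusted p = 0.441 with an estimated correlation), and 13 of 30 adipocyte genes were lower (camera adjusted p = 1.63e-11; adjusted p = 0.441 with an estimated correlation). Cdkn2a was lower, at 37.6 ± 1.38 against 58.4 ± 3.34 CPM (adjusted p = 0.0053). Upper-quartile scaling changed the share of higher calls from 50.7% to 38.6%, and the 1887 calls became 2 without DKO replicate 1, 16 without Ing1-KO replicate 2, 138 without DKO replicate 2, 298 without Ing1-KO replicate 1, 3215 without Ing1-KO replicate 3, 1069 without WT replicate 3 and 1200 without Gadd45a-KO replicate 3. They were 1081 with no filter, 2924 by DESeq2, 1227 when only the 6 libraries compared were fitted, 304 at a fold of at least 2 and 3 with the adipocyte score as covariate.

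In 96 genes the libraries labelled DKO differed in the same direction from all 3 other genotypes, 65 higher and 31 lower. Slc40a1, the iron exporter ferroportin, was at 71.7 ± 3.10 CPM against 28.6 ± 3.04 in WT, 34.1 ± 6.13 in the libraries labelled Gadd45a-KO and 44.3 ± 5.26 in Ing1-KO. Adcyap1r1, a neuropeptide receptor, was at 1.94 ± 0.326 CPM against 8.61 ± 1.09, 6.02 ± 1.43 and 6.65 ± 0.601 CPM, and Nod1, a sensor of bacterial peptides, at 14.5 ± 1.58 CPM against 30.6 ± 3.21, 23.9 ± 3.81 and 28.1 ± 2.36 CPM. The highest edgeR adjusted p-value of these 3 genes was 0.028. Adcyap1r1 and Nod1 lie within 20 Mb of Gadd45a in the reference annotation, where 46 of 217 tested genes were called between the libraries labelled DKO and Ing1-KO (21.2%, against 11.9% elsewhere; two-sided Fisher exact p = 0.000126, adjusted over 18 tests p = 0.00227). Within 10 Mb 12 of 63 were called (adjusted p = 0.161 by the same Fisher exact test) and within 5 Mb 5 of 28 (adjusted p = 0.422), neither of which passed. The Fisher test treats genes as independent, although genes vary together, so its p-values may overstate a cluster. No other windows of these sizes were taken as a reference. Between the libraries labelled Gadd45a-KO and WT, where edgeR called 2 genes in all, 1 of the 217 was called, E230016M11Rik. Rasgrp3, Slc16a7, Rnf128 and Slc8a1 were the other rises taken by the rule, and Syt13, Npy1r and Atp9a the other falls. The 96 became 52 with the replicate number as a block, 720 by DESeq2, 10 at a fold of at least 2 and 1 with the adipocyte score as covariate. They became 51, 49 and 38 without WT replicates 1, 2 and 3, 228, 41 and 29 without Gadd45a-KO replicates 1, 2 and 3, 6 and 338 without Ing1-KO replicates 2 and 3, and 0, 5 and 278 without DKO replicates 1, 2 and 3.

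The interaction asked whether the change in the libraries labelled DKO differed from the sum of the changes in the single mutants. No gene was called by edgeR, with 2204 at an unadjusted p under 0.05, where chance gives 808, and a smallest adjusted p of 0.0692. DESeq2 called 173 and limma-voom 0, and without Ing1-KO replicate 3 edgeR called 191, without DKO replicate 3 30 and without WT replicate 3 1. On simulated data the interaction recovered 35.8% of genes changed 1.5-fold, 61.2% of those changed 2-fold and 83.3% of those changed 4-fold, among 16163 genes. The changed genes were a random draw with independent noise, so these shares need not hold for genes that spread widely between libraries. Of 30 adipocyte identity genes, with an interaction median of -1.50 on the log2 scale, none was called. The 2 genes called between the libraries labelled Gadd45a-KO and WT were not called in Ing1-KO, so the single mutants shared no call (3 by DESeq2, 7 without Gadd45a-KO replicate 1 and 1 without WT replicate 3 or Ing1-KO replicate 2). Ing1-KO and the libraries labelled DKO shared 113 higher and 166 lower calls against WT, with 2 in opposite directions. Lists of the same lengths drawn independently would share 23.0 and 22.1. Unchanged groups simulated against shared WT libraries shared 0 and 0.025, but such groups give almost no calls at all. Both real comparisons use the same WT libraries and genes vary together, so neither value is the overlap to be expected of these lists. The covariance of log2 fold changes across genes, which are not independent replicates, was 0.104 against 0.026 in the simulations, while Pearson's r, 0.519, lay within the simulated range, with a mean of 0.496 and a maximum of 0.535. Between the libraries labelled Gadd45a-KO and Ing1-KO the covariance was 0.0374 against 0.0259, and r 0.43 against 0.5. Between the libraries labelled Gadd45a-KO and those labelled DKO, both compared with WT, the covariance was 0.0899 against 0.0259, and r, 0.635, lay above the simulated range, with a mean of 0.495 and a maximum of 0.521.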

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

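The list tests of the interaction were fixed before the data were examined; every test of an explanation in this part was chosen after the values it bears on had been seen.

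For 11 gene lists the change in the libraries labelled DKO differed from the sum of the single mutants' changes by camera, and for none with an estimated correlation (adjusted p from 0.428 to 0.745). The interaction medians on the log2 scale were -1.50 for adipocyte identity (adjusted p = 0.000111), -0.14 for anti-adipogenic factors (0.0087), -0.74 for brown and beige markers (0.000348), 0.24 for contractile genes (5.12e-06), 0.31 for TGF-beta and SRF response (1.03e-06), 0.64 for leukocyte markers (1.72e-09), 0.35 for proliferation (2.05e-18), -0.084 for p53 targets (0.017), -0.65 for acute phase proteins (0.00443), -0.14 for imprinted genes (0.00227) and -0.17 for positional genes (0.00268). Single libraries decided some of these calls and sizes. Without Ing1-KO replicate 1 the medians of the adipocyte identity and acute phase lists were -0.32 and -0.25 and not called (camera adjusted p = 0.225 and 0.345), and those of the brown and beige, contractile and imprinted lists -0.32, 0.15 and -0.07. Without Ing1-KO replicate 3 the positional list was not called (median -0.20, adjusted p = 0.0543), and the brown and beige median was -1.14. The p53 list was not called without WT replicate 1 (-0.064), Gadd45a-KO replicate 1 (-0.03), Ing1-KO replicate 3 (-0.045) or DKO replicate 3 (-0.085), and its median was -0.13 without Gadd45a-KO replicate 2. Without Gadd45a-KO replicate 1 the leukocyte and imprinted medians were 0.32 and -0.09, without WT replicate 3 the brown and beige median -1.12, without DKO replicate 2 the contractile median 0.13, and without Ing1-KO replicate 2 the positional median -0.27. By edgeR no single gene passed the test of the interaction over all genes, with 2204 at an unadjusted p under 0.05, where chance gives 808, and 173 called by DESeq2.

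Gadd45a reads were 9.02 times higher in the 6 libraries labelled Gadd45a-KO or DKO than in the other 6. A single wrong label is argued against by the ratio of 7.49 between the lowest of those 6 and the highest of the others. Transcription from the targeted allele or its inserted sequence, which may also touch E230016M11Rik (log2 fold change -3.03), and an exchange of the Gadd45a labels over the whole set cannot be told apart, because counts per gene do not show which exons were read. No biological explanation was tested.

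Adipocyte genes spread widely among the Ing1-KO libraries, with Fabp4 between 98.8 and 1219 CPM. Replicate 3 as a mislabelled DKO library is argued against by its Gadd45a level, 13.4% of the lowest library labelled DKO, and a difference in library size by the factor of 1.09 between the Ing1-KO libraries. Cultures that differentiated to a different extent remain a candidate explanation. Across all tested genes, the difference between replicates 1 and 3 went with that between WT and the libraries labelled DKO (Pearson r = 0.586). Replicates 1 and 3 are the extremes in adipocyte genes, which also differ between WT and DKO. The correlation therefore partly restates the spread and cannot tell this cause from others. Genes are not independent replicates. No explanation by genotype was tested, since all 3 share it.

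Leukocyte markers were higher in the libraries labelled DKO than in WT; of the most abundant, Lyz2, which shares sequence with Lyz1 and is uncertain, was at 4646 against 2813 CPM (edgeR adjusted p = 0.183) and Mpeg1 and Mrc1 at 565 against 283 CPM and 500.2 against 203 CPM (adjusted p = 0.0299 and 0.0287). Lyz2 and Mpeg1 were chosen for their abundance after their values were seen. A lower share of adipocytes could raise every other cell type alike. The upper quartile of log2 fold changes of the fibroblast list, 0.05, lay below the lower quartile of the leukocyte list, 0.84. The contractile list did rise, with all 25 tested members positive and a median of 0.39. The lists thus did not rise alike. Whether adipocytes in these cultures also express the matrix genes was not measured, so the fibroblast list cannot exclude a lower share of adipocytes. That 100% of the 25 tested markers, none of them in another list, lay above 0 restates the pattern and tests no cause. The markers varied together (estimated correlation 0.864). Against WT, 23 of 25 lay above 0 in the libraries labelled Gadd45a-KO and 19 in Ing1-KO, where the list was not called (camera adjusted p = 0.157 and 0.507). A lower share of adipocytes, a larger share of leukocytes in these cultures and a change of expression within cells all stay open, and so does the genotype.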

How the results depend on the processing

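The adipocyte score as covariate, limma-voom, fits of lists to the 6 libraries compared, and most settings of the overlap were chosen after the data had been seen; the other alternatives were fixed before. RLE and upper-quartile factors, the legacy fit and limma-voom kept every count of calls within 1.5 times, and the largest shift of the median of all genes by scaling was -0.0353, for the interaction with upper-quartile factors. For the other changes given here the cause was not tested, unless fewer genes or samples entered by construction.

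By DESeq2, counts became 3 higher and 4 lower for the libraries labelled Gadd45a-KO against WT, 645 and 611 for Ing1-KO against WT, 1253 for DKO against Gadd45a-KO, 2924 for DKO against Ing1-KO, 173 for the interaction, 720 apart in DKO and 3 shared by the single mutants. With no filter they became 2 lower in Gadd45a-KO, 1081 for DKO against Ing1-KO, 1 interaction and 1 shared call, and at a mean of at least 5 CPM 0 lower in Gadd45a-KO, whose lower gene lies under that level. A fold of at least 2 left 109 and 41 for Ing1-KO, 168 and 360 for DKO against WT, 35 and 304 for DKO against Gadd45a-KO and Ing1-KO, and 10 apart. Only the 6 libraries compared gave 217 and 171 for Ing1-KO, 1487 higher for DKO against WT, 424 and 1227 for DKO against Gadd45a-KO and Ing1-KO. Within 20 Mb of Ing1, 10.7% of genes were called in Ing1-KO, past the threshold by a Fisher test that treats genes as independent.

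Camera called 14, 14, 14, 14, 18 and 11 lists in the libraries labelled Gadd45a-KO, Ing1-KO and DKO against WT, DKO against Gadd45a-KO, DKO against Ing1-KO and the interaction. An estimated correlation called 0 in each, and fry 0, 8, 12, 0, 3 and 0. For DKO against WT fry lost oxidative phosphorylation (fry adjusted p = 0.0568), contractile genes and acute phase proteins (0.0776 for both). It kept the other camera calls, such as adipocyte identity (0.0159) and leukocyte markers (0.0445), and added fibroblast genes as lower (0.0365). For Ing1-KO it lost adipocyte identity (0.194), fatty acid synthesis (0.0871), triglyceride genes (0.196), TGF-beta response (0.245), p53 targets (0.0747) and glucocorticoid response (0.0692).

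Same-numbered replicates did not deviate together: 2 of 18 pairs had a correlation over 0.1 (from -0.189 to 0.251), and 5 of 12 libraries correlated best with their own number. With the replicate number as a block, DKO against Gadd45a-KO had 95 calls, 52 genes were apart in DKO, and no other count of calls moved by over 1.5 times.

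Leaving out each library in turn gave from 1 to 30 higher and 1 to 3 lower in Gadd45a-KO against WT, 63 to 698 and 38 to 539 in Ing1-KO, 121 to 1472 and 173 to 1472 in DKO, 6 to 590 for DKO against Gadd45a-KO, 2 to 3215 for DKO against Ing1-KO, 0 to 191 interactions, 0 to 338 apart and 0 to 7 shared. Lists called ranged from 12 to 17, 12 to 20, 13 to 16, 11 to 15, 16 to 19 and 10 to 16. Over the named genes, fits without a library 485 times took a call below the threshold and 10 times took a gene past it. No called named gene changed sign in these fits. The p53 targets list median ranged from -0.002 to 0.069 in Gadd45a-KO against WT, the lowest without Gadd45a-KO replicate 1.

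The adipocyte score is itself an outcome of the genotypes and holds the adipocyte list's own genes, so it removes what it measures. With it, 2 genes were lower in Gadd45a-KO, 780 higher and 808 lower in Ing1-KO, 20 and 25 in DKO against WT, 69 and 3 for DKO against Gadd45a-KO and Ing1-KO, 6 in the interaction, 1 apart and 1 shared. Log2 fold changes in DKO against WT changed sign to -0.074 for Cxcr4, 0.233 for Pparg, 0.039 for Srebf1, 0.14 for Lipe, 0.238 for Gpat3, 0.152 for Cpt2, 0.057 for Cycs, 0.036 for Atp5b, 0.024 for Ndufv1, 0.042 for Akt2, -0.02 for Tpm1, -0.02 for Pecam1, 0.054 for Eng, 0.562 for S100b, 0.05 for Csf1, 0.07 for Steap4, 0.32 for Hp, 0.066 for Dnajb9, 0.315 for Pdk4, 0.102 for Fabp4, and that of Slc2a4 in Ing1-KO against WT to 0.648. List medians or directions also changed sign. For Gadd45a-KO against WT, they became 0.06 for adipogenic factors, 0.078 for brown and beige markers, 0.048 for acute phase proteins. For DKO against WT, they became 0.091 for adipogenic factors, 0.021 for fatty acid synthesis, 0.178 for triglyceride genes, 0.315 for brown and beige markers, 0.214 for fatty acid oxidation, 0.117 for oxidative phosphorylation, -0.099 for contractile genes, 0.879 for acute phase proteins, 0.043 for glucocorticoid response. For DKO against Gadd45a-KO, they became 0.09 for adipogenic factors, 0.076 for fatty acid synthesis, 0.254 for triglyceride genes, 0.018 for cholesterol synthesis, 0.338 for brown and beige markers, 0.297 for fatty acid oxidation, 0.142 for oxidative phosphorylation, -0.016 for contractile genes, -0.055 for TGF-beta response, 0.613 for acute phase proteins. For DKO against Ing1-KO, they became -0.015 for adipocyte identity, 0.021 for adipogenic factors, 0.095 for fatty acid synthesis, 0.246 for triglyceride genes, 0.11 for cholesterol synthesis, 0.112 for fatty acid oxidation, 0.02 for oxidative phosphorylation, 0.206 for acute phase proteins. For the interaction, they became 0.03 for adipocyte identity, 0.197 for acute phase proteins.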

Other observations

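The windows around the targeted genes and the gene lists were fixed before the data were examined; the strain hypothesis and the tests by other splits of the libraries were set out after the results had been seen.

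In Ing1-KO, further genes and groups moved against WT. Il1rn, the interleukin-1 receptor antagonist, rose from 38.5 ± 10.4 to 115 ± 13.1 CPM (edgeR adjusted p = 0.00381), Igfbp2, an IGF binding protein, from 254 ± 6.72 to 432 ± 19.9 CPM (adjusted p = 0.00431), and Mecom, a transcription factor, from 7.15 ± 0.516 to 30.0 ± 9.57 CPM (adjusted p = 0.00244). Ccl2 and Ccl7, which attract monocytes, fell by 0.47 and 0.42 on the log2 scale (adjusted p = 0.00788 and 0.00654). Of 18 neural and Schwann cell markers none was called by edgeR, but adjusted over the list alone 9 fell and 1 rose (camera adjusted p = 0.000205; adjusted p = 0.282 with an estimated correlation). Of 33 p53 targets 2 rose and 1 fell (camera adjusted p = 0.00111; adjusted p = 0.428 with an estimated correlation), and of 26 fatty acid synthesis genes 3 fell (camera adjusted p = 4.73e-07; adjusted p = 0.395 with an estimated correlation). Of 21 triglyceride genes none was called by edgeR (camera adjusted p = 9.67e-05; adjusted p = 0.554 with an estimated correlation). The list of DNA methylation genes and the ING and GADD45 families, which holds Ing1 itself, was called as lower (camera adjusted p = 0.00255; adjusted p = 0.282 with an estimated correlation), with a mean log2 fold change of -0.16 but a median of 0.02.

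In the libraries labelled DKO against WT, 8 of 25 adipogenic transcription factors fell (camera adjusted p = 1.32e-05; adjusted p = 0.314 with an estimated correlation) and 8 of 23 brown and beige markers (camera adjusted p = 3.08e-08; adjusted p = 0.312 with an estimated correlation). Of 31 senescence and inflammatory genes 6 fell and 1 rose (camera adjusted p = 0.00121; adjusted p = 0.298 with an estimated correlation), and of 23 glucocorticoid and cAMP response genes 5 fell (camera adjusted p = 0.00187; adjusted p = 0.309 with an estimated correlation). Camera did not call the lists of oxidative stress genes (3 up and 6 down of 26, adjusted p = 0.11), fibroblast and matrix genes (2 and 6 of 39, 0.0893), insulin and IGF signalling (3 and 4 of 29, 0.239), TGF-beta and SRF response (1 and 0 of 21, 0.0513), integrated stress (5 and 1 of 30, 0.664), DNA methylation and the ING and GADD45 families (3 and 3 of 37, 0.807), anti-adipogenic factors (0 and 2 of 26, 0.744) or interferon response (0 and 1 of 42, 0.664). The endothelial (3 and 2 of 15, 0.752), skeletal muscle (0 and 1 of 16, 0.752) and epithelial (0 and 1 of 8, 0.672) lists were not called either, nor were imprinted genes (4 and 2 of 27, 0.266), positional genes (1 and 6 of 49, 0.6), neural and Schwann cell markers (1 and 1 of 18, 0.174), p53 targets (3 and 1 of 33, 0.146) or proliferation genes (0 and 0 of 35, 0.672). Median, mean and test differed in sign for the interferon (-0.01, 0.04, up), integrated stress (-0.01, 0.03, up), skeletal muscle (-0.03, -0.15, up), epithelial (0.04, -0.17, down), positional (0.05, -0.05, down) and DNA methylation (0.04, -0.05, up) lists.

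Genes on the Y chromosome were read in all 12 libraries, Ddx3y between 128 and 170 CPM. Xist, expressed from the inactive X, had 193 reads in WT replicate 1 (4.02 CPM) and between 0 and 13 in the other 11.

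Sequence of another strain beside the targeted Ing1 allele is a hypothesis for calls near it. Within 10 Mb of Ing1, 8 of 87 tested genes were called in Ing1-KO against WT (9.2%), against 4.41% elsewhere (two-sided Fisher exact p = 0.0582, adjusted over 18 tests p = 0.0952), and within 20 Mb 16 of 149 (p = 0.00096, adjusted p = 0.00864). For the same allele and 20 Mb, 24 of 149 were called in the libraries labelled DKO against WT (16.1%, against 13.3% elsewhere; two-sided Fisher exact p = 0.332, adjusted over 18 tests p = 0.421), and 7 of 149 in DKO against Gadd45a-KO (4.7%, against 1.25%; p = 0.00311, adjusted p = 0.014). In DKO against Gadd45a-KO 3 of 87 were called within 10 Mb (two-sided Fisher exact p = 0.101, adjusted p = 0.152) and 3 of 48 within 5 Mb (p = 0.0235, adjusted p = 0.0529). In DKO against WT these windows held 18 of 87 and 11 of 48 (adjusted p = 0.0952 for both), and in Ing1-KO against WT 3 of 48 lay within 5 Mb (two-sided Fisher exact p = 0.472, adjusted p = 0.5). Within 20 Mb of Gadd45a, 41 of 217 were called in the libraries labelled DKO against WT (18.9%, against 13.3% elsewhere; two-sided Fisher exact p = 0.0204, adjusted over 18 tests p = 0.0525), 11 of 63 within 10 Mb (adjusted p = 0.421) and 4 of 28 within 5 Mb (adjusted p = 0.783). In the libraries labelled Gadd45a-KO against WT, 1 of 217 was called within 20 Mb, 1 of 63 within 10 Mb and 1 of 28 within 5 Mb (two-sided Fisher exact adjusted p = 0.042, 0.0146 and 0.0108). Each time this was E230016M11Rik, which overlaps Gadd45a. No other gene in these windows was called, but the comparison had 2 calls in all, so it could hardly show a cluster. All these Fisher tests treat genes as independent, although genes vary together, and no other windows were taken as a reference. Their p-values may therefore overstate a cluster. Flanking sequence may contribute, but counts hold no variants, so other causes of a cluster of calls cannot be told apart from it.

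Other splits of the libraries were fitted in the same way. The 10 splits of 6 libraries are too few for a share under 0.05. Every split but the real one also mixes both genotypes in each group. Where the genotypes differ this raises the spread within groups, so low counts in the other splits say little about chance. The real and highest other counts were 2 and 0 for the libraries labelled Gadd45a-KO against WT, 699 and 284 for Ing1-KO against WT, 2106 and 0 for the libraries labelled DKO against WT, 203 and 0 for DKO against Gadd45a-KO, and 1887 and 1 for DKO against Ing1-KO. The split with 284 calls grouped WT replicate 2 with Ing1-KO replicates 2 and 3. Of 100 splits drawn from the 12 libraries, all 100 gave at least the 0 interaction calls of the real one, which any split does, so this says nothing about chance. In 3 of the other draws 3, 64 and 192 genes were called. Shuffled labels can line up with the real differences between genotypes, so these calls need not point to any other structure. Their cause was not tested. For genes apart from all 3 other genotypes, 1 of 100 splits, the real one with 96, reached that count and the highest other gave 1. The draws mix genotypes that differ, which raises the spread within their groups and leaves few calls whatever the cause. They therefore do not exclude chance for the 96 genes, and without DKO replicate 1 the count was 0.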
